A study of Mus musculus with 4 samples.

How the data were processed

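The study used 4 two-colour Agilent whole-genome expression arrays. TRP-1 CD4+ T cells, which carry a transgenic T cell receptor against the melanocyte antigen tyrosinase-related protein 1, were given to tumour-bearing RAG-deficient mice and recovered after 1 week from spleens or lymph nodes, pooled within each organ. Each array set the recovered RNA against RNA of naive TRP-1 CD4+ T cells. The spleen RNA was on 2 arrays and the lymph node RNA on 2 arrays, with the dyes exchanged within each pair: the transferred cells were in Cy3 on array 1 and in Cy5 on array 2 of each organ, per the labels. All 4 arrays were on 1 slide and in 1 scan, per the file headers, so slide and scan did not differ between the organs.

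The deposited scanner files hold spot intensity on a linear scale for both channels, with local background, flags and processed signals, written by Agilent Feature Extraction 9.5.3.1, per the submitters' processing notes. The deposited series table holds a log10 ratio per spot. It was within 0.01 of the scanner files' log10 ratio on 100.0% of spots on each array, after the sign was turned on the arrays with the transferred cells in Cy3, so it runs as transferred over naive on all 4. Its medians per array were 0.0000, 0.0000, 0.0027 and 0.0048 on the log10 scale for spleen array 1, lymph node array 1, spleen array 2 and lymph node array 2. It was used as an alternative only. Further details of the authors' processing are not given in the sources used here.

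From the intensities, the background was corrected with normexp (mean signal, local background median, offset 50) and each array was normalized within itself by loess, with limma 3.58.1 in R 4.3.3. Control spots and spots flagged as outliers had no weight in the loess. The flagged spots, 120 to 170 among the 43379 measurement spots per array, were then left out, and spots of the same probe were averaged. Saturated spots were kept: 1 on spleen array 2 and 1 on lymph node array 2. All ratios were turned to transferred over naive. Of 41174 probes, 32438 had 1 gene name, from the platform annotation with symbols updated through a RefSeq gene table of GRCm38.p6, or from an accession, and the other 8736 were left out of the gene counts. A probe was kept if it was well above background on all arrays of at least 1 of the 3 RNAs (naive, spleen, lymph node), which 32981 probes were. The share of probes well above background in the channel of the transferred cells was 77.2% and 85.5% on spleen arrays 1 and 2, and 76.2% and 84.5% on the lymph node arrays, and in the naive channel 87.2% and 77.7%, and 88.6% and 75.0%. The Cy5 channel was the higher of the 2 on every array. The probe with the highest mean signal stood for its gene, which left 17267 genes. Of these, 2271 had another probe of opposite sign, among them 523 of the genes called changed. Probe coordinates are those of the files, on mouse build mm7.

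The arrays of a pair hold the same 2 RNAs and were averaged, so each organ counted as 1 sample. The median SD within a pair was 0.107 (log2) in spleen and 0.103 in lymph node. The main test was limma's lmFit and eBayes with an intensity trend on the 2 organ means, against 0, two-sided, with Benjamini-Hochberg adjusted p under 0.05. It has 1 residual degree of freedom per gene plus 2.611 from the prior. The SE given with a mean of the organs is limma's moderated SE, in which a gene's own spread is drawn towards that of genes of like signal. It is smaller than the SE of the 2 organ means alone for genes far apart between the organs, such as S100a9 (-4.28 in spleen, -7.18 in lymph node). For genes whose organ means lie close, such as Cxcr6 (4.06 and 4.14), it is larger. The p-value measures the spread between the 2 organs. It leaves out the spread between naive samples, since the same naive RNA is in every ratio, and the labels do not say whether spleens and lymph nodes came from different mice. For each organ, and for lymph node against spleen, there is 1 sample a side and no test. Genes were counted there if the log2 ratio was at least 1 in size on both arrays, or in both dye orientations, which is 2-fold.

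The calculation was tested on simulated data for the comparison of transferred with naive cells in both organs, with 17267 genes and 200 of them changed. A log2 change of 1 was called in 98.5% of the 200 genes, and changes of 2 and 3 in 100.0%. With no gene changed, 1 gene was called, and with changes of 1, 2 and 3 in 200 genes 34, 43 and 57 unchanged genes were called. The naive sample was then also given a random deviation as large as that of an organ sample. With none changed, 245 of 17267 genes were called there. With changes of 1, 2 and 3, 565, 500 and 376 unchanged genes were called, at most 3.31% of the unchanged genes. These stood beside 194, 200 and 200 changed genes called, so most calls were false. Without that deviation 197, 200 and 200 changed genes were called. In neither case did the adjusted p threshold hold the share of false calls at its nominal level. The share of false calls in the real data was not estimated.

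Named genes followed a rule fixed before the data were examined: the 10 highest and 10 lowest mean log2 ratios among genes past the test with the same sign on 4 arrays, the 5 highest and 5 lowest of each organ by the weaker array, the 10 highest and 10 lowest of lymph node against spleen by the weaker orientation, and members of 31 fixed gene lists in the account of their list. For each list the members that rose or fell are given over all genes and adjusted over the list alone, and its median is placed among 10000 random lists of the same size drawn from the same signal deciles, as a description with no p. Alternatives covered the background, normalization, filter, probe rule, source table, saturated probes, each array left out, the model and the size rule. An alternative in which the median of the T cell identity list is subtracted on each array was added after seeing the data. Its limma adjusted p fell to 1.28e-133 (S100a9) from 2 organ means, so the degrees of freedom above do not describe that fit. Klk1b5 lay at 2.89 in spleen and 0.37 in lymph node there. Its limma adjusted p was 1.35e-06, against 0.0501 in the main test. Calls on that scale thus hardly weigh a gene's own spread between the organs. There 16598 of 17267 genes were lower, with a median of -1.67 over all genes, so a lower call alone says little. The genes named were well above background on all arrays of all 3 RNAs, except Siglech in the naive RNA (3 of 4 arrays) and Ccl22 in the naive and spleen RNA (no array). For Ccl22 the lymph node level was therefore set against a floor in spleen, the higher of its own signal and the lowest signal among probes well above background on that array, with channel levels taken after loess and Aquantile, which gives a lower bound. Among the genes named, Cd44, Ighm, Il2, Nrp2, Runx2, Trat1 and Zeb2 had another probe of opposite sign. Values of some list members are not reported here.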

Results

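RNA of TRP-1 CD4+ T cells was compared with RNA of naive TRP-1 CD4+ T cells after the cells had spent 1 week in tumour-bearing RAG-deficient mice. About 1000000 cells were sorted per organ after a transfer of 200000, given on day 7 to 10 of tumour growth. There were 2 arrays for spleen and 2 for lymph node, each pair a dye exchange of the same RNAs, and 17267 genes were tested. The precision is limited by the number of samples, which is 1 per organ.

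The first comparison asks how the transferred cells of both organs differed from naive cells. The highest ratio belonged to Cxcr6, a chemokine receptor of effector T cells, with a log2 ratio of 4.10 ± 0.11 (limma's moderated SE, n = 2 organs, limma adjusted p = 0.0027), which is 17.1-fold. S100a4, a calcium-binding protein, followed at 3.83 ± 0.11 and Il18r1, a chain of the interleukin 18 receptor, at 3.51 ± 0.30. Ms4a4b (3.07), Ctla2a (3.05), Emp1 (2.99), the lectin gene Lgals1 (2.96), the transcription factor gene Runx2 (2.95), the receptor gene Slamf1 (2.92) and Epsti1 (2.92) completed the 10 highest among genes past the test. Klk1b5 had a mean of 3.27 and was above 0 on all 4 arrays, but it just missed the threshold (limma adjusted p = 0.0501). Another probe of Runx2 had the opposite sign. The lowest ratios belonged to genes of granulocytes and red cell precursors. S100a9, a neutrophil calcium-binding protein, fell by 5.73 ± 0.77 (adjusted p = 0.0161) and Rhd, a blood group antigen gene, fell by 5.55 ± 0.15 (adjusted p = 0.0027). The others were Tal1 (-5.50), Chil3 (-5.48), the antimicrobial peptide gene Camp (-5.47), the myeloperoxidase gene Mpo (-5.43), the amino acid transporter gene Slc38a5 (-5.24), Gfi1b (-5.18), the cathepsin G gene Ctsg (-5.15) and Hemgn (-5.10). The Cxcr6 probe lies on chromosome 9 from 123530288 to 123530347, and the S100a9 probe on chromosome 3 from 90822865 to 90822924 (mm7). In all, 5802 genes changed, of which 2262 rose and 3540 fell, and 1699 of them by at least 2-fold (613 higher, 1086 lower). With the 4 arrays entered as separate samples, 12954 genes passed, 5741 of them higher. When every array was centred on the T cell identity genes, a choice made after seeing the data that lowered the median of all genes to -1.67, 16646 genes passed, 48 higher and 16598 lower, and 46 of the 48 were among the 2262. The p-values of that fit hardly follow a gene's own spread between the organs, so its count and the 5802 do not compare directly.

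**Figure D1:**
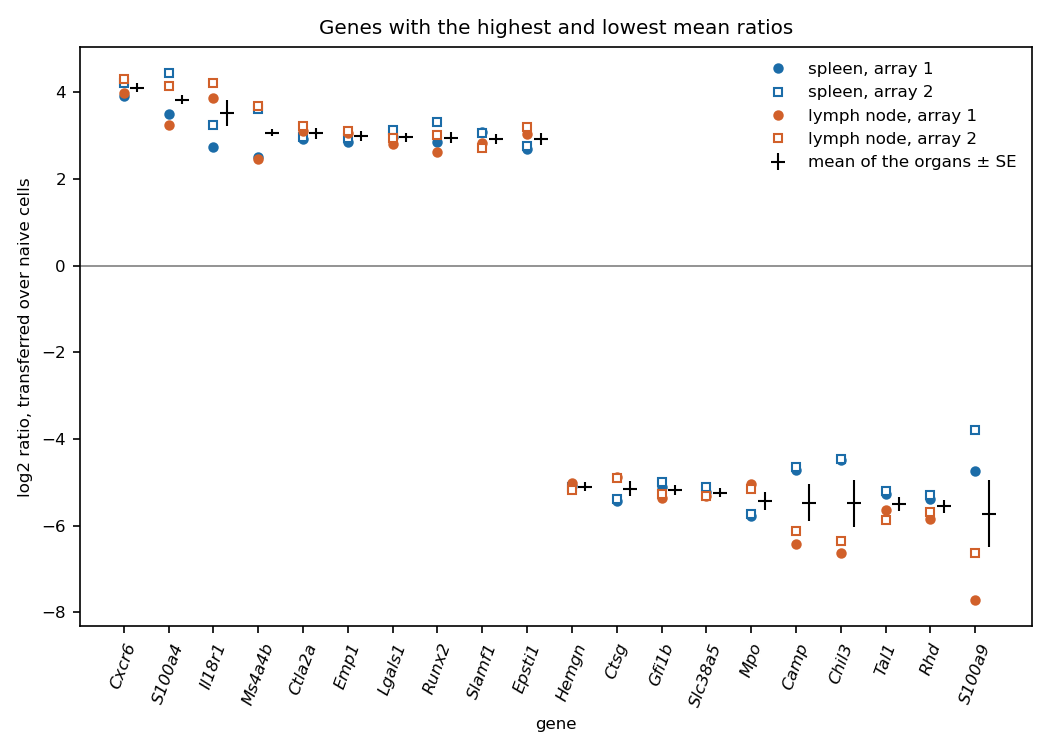
Log2 ratio of transferred over naive cells (vertical axis) for the 10 genes with the highest and the 10 with the lowest mean ratios among genes past the test. Each of the 4 arrays is a point, and the mean of the 2 organs ± limma's moderated SE is a bar. The values of the 4 arrays lie on the same side of 0 for all 20 genes, as the rule that chose them required. S100a9 shows the widest gap between the organs, at -4.28 in spleen and -7.18 in lymph node.

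Erythroid and neutrophil genes fell as whole lists and most T cell identity genes rose, while B cell and macrophage genes fell in part over naive cells. Relative to the T cell identity list B cell and macrophage genes were all lower, as were nearly all genes tested. All 12 measured erythroid genes fell, with a median log2 ratio of -2.77 (-2.59 in spleen, -3.01 in lymph node). They included Car2, a carbonic anhydrase of red cells (-4.29), the haemoglobin gene Hba-a1 (-3.54) and the erythroid transcription factor gene Klf1 (-3.45). All 12 neutrophil genes fell as well, with a median of -4.02, among them Ltf (-4.28) and Elane (-2.37). Both counts were the same adjusted over the list alone, and both medians lay below those of all 10000 matched random lists. Of 15 T cell identity genes, 13 rose, the same number adjusted over the list alone, with a median of 1.58 (1.81 in spleen, 1.46 in lymph node). Thy1, a surface marker of T cells, rose by 2.20 ± 0.12, the signalling kinase gene Lck by 1.89, the T cell receptor chain gene Cd3d by 1.86 and Cd4 by 1.58. Cd3e (0.15) and Trat1 (-0.10) did not pass. In the B cell list 5 of 12 genes fell and 1 rose (7 and 1 adjusted over the list alone), led by Ighm at -4.17, which has another probe of opposite sign. In the macrophage and monocyte list 7 of 17 fell and none rose, the same adjusted over the list alone, led by Lyz2 (-3.88) and Lyz1 (-3.64). All 12 B cell and all 17 macrophage and monocyte genes were lower relative to the T cell identity list, with medians of -1.88 and -1.92. On that scale 16598 of 17267 genes were lower and the median of all genes was -1.67, so this says little about these 2 lists. The medians of the T cell, erythroid and neutrophil lists come from the same arrays and the same naive RNA as those of every group that follows.

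Genes of the Th1 programme rose with the T cell genes. Of 20 measured Th1 genes 11 rose and none fell, the same adjusted over the list alone, with a median of 1.11 that becomes -0.53 relative to the T cell identity list. On that scale 7 members were higher and 9 lower. Besides Il18r1 the 7 included Havcr2, an inhibitory receptor of Th1 cells (2.84 ± 0.11), the chemokine receptor gene Cxcr3 (2.67), the interferon gamma gene Ifng (2.38 ± 0.56, adjusted p = 0.0491, and 0.0503 to 0.0696 without background correction, without the normexp offset or without the intensity trend), Tbx21, the master transcription factor of Th1 cells (2.34), and Il12rb1 (2.31). Ifng was at 1.57 in spleen and -0.10 in lymph node relative to the T cell list. Its limma adjusted p of 0.0145 on that scale does not reflect this gap between the organs. Stat4 rose by 1.88 and Il12rb2 by 1.20, but relative to the T cell list Stat4 did not pass (0.24, adjusted p = 0.442) and Il12rb2 was at -0.44. Tnf (0.42), Ccl5 (0.32) and Il2 (-0.03) did not pass. Among 15 cytotoxic effector genes 10 rose and 1, Lamp1, fell (adjusted p = 0.109 with median centring and 0.0597 without lymph node array 1), the same adjusted over the list alone, with a median of 1.43 or -0.21 relative to the T cell list. Granzyme B (Gzmb, 2.50) and granzyme D (Gzmd, 2.34) rose on both scales, and 6 members were lower on the second. Gzmc (2.25), Serpinb9 (2.00), an inhibitor of granzyme B, and Fasl (1.43) rose over naive cells and did not pass relative to the T cell list, where Fasl was at -0.21, while the perforin gene Prf1 (0.02) and Gzma (0.20) did not pass. Of 23 trafficking genes 12 rose and 2 fell (13 and 3 adjusted over the list alone), with a median of 1.07, or -0.57 relative to the T cell list. Cxcr6, Cxcr3 and the integrin gene Itgb1 (2.67) rose on both scales, 11 members were lower relative to the T cell list, and Cxcr4 (-0.71, adjusted p = 0.0622 with median centring) and S1pr5 (-1.85) fell over naive cells.

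**Figure D2:**
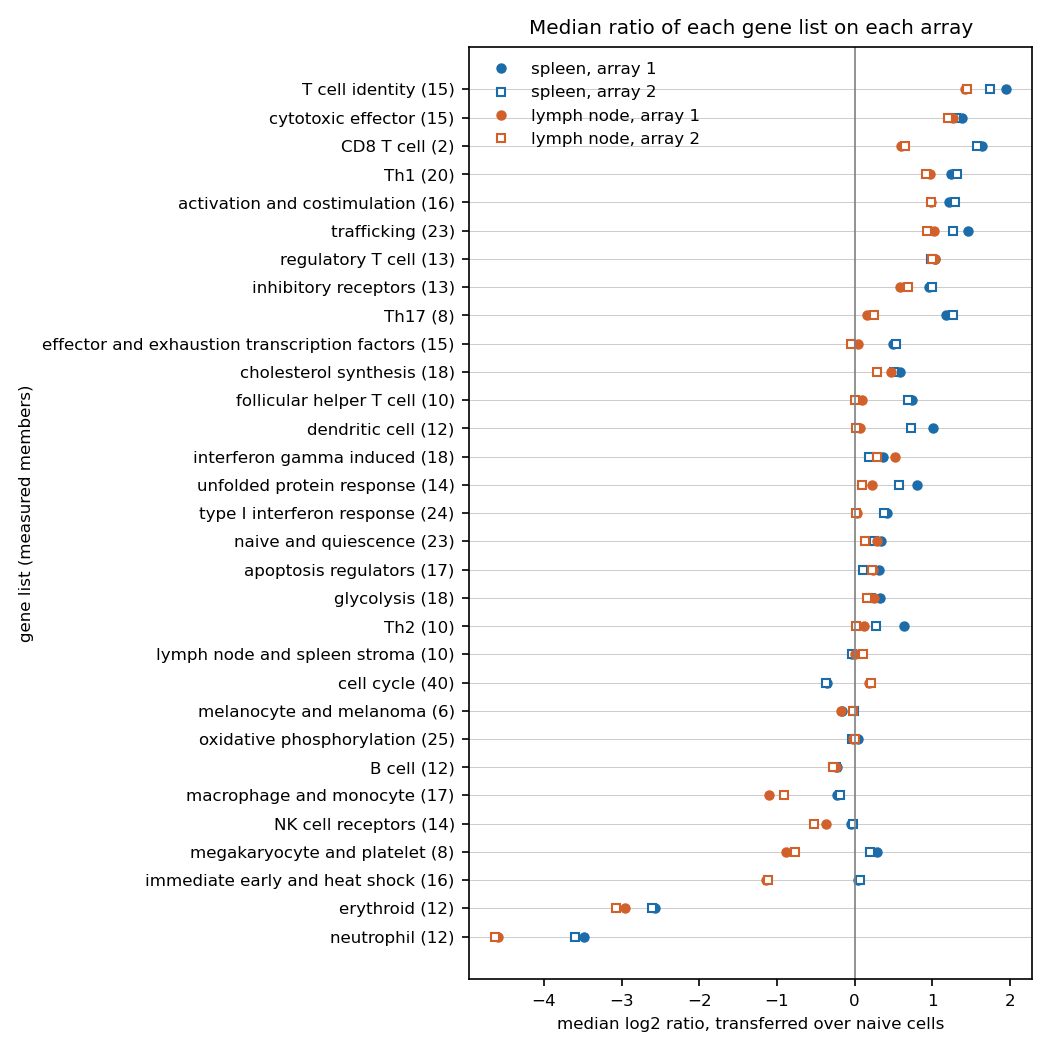
Median log2 ratio of transferred over naive cells (horizontal axis) for each of the 31 gene lists on each array, with the number of measured members in brackets. Neutrophil and erythroid genes lie lowest on all 4 arrays, with medians over the organs of -4.02 and -2.77, and T cell identity genes highest at 1.58, which the scale relative to that list sets to 0.

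Other T cell programmes moved in part. In the activation and costimulation list 12 of 16 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 1.08, or -0.56 relative to the T cell list. Cd28 (2.18), Icos (2.11) and Il2rb (2.01) rose, Tfrc, the transferrin receptor gene that the erythroid list also holds, fell by 1.39, and Cd44 was at 0.15 and Cd69 at 0.28 without passing. Of 13 inhibitory receptor genes 7 rose and none fell (7 and 1 adjusted over the list alone), with a median of 0.76, or -0.88 relative to the T cell list. These included Havcr2, Ctla4 (1.85) and Entpd1 (1.27), while Pdcd1 (0.71) and Lag3 (0.76) did not pass. Among 15 effector and exhaustion transcription factors 7 rose and 2 fell, the same adjusted over the list alone, with a median of 0.62, or -1.02 relative to the T cell list. Id2 rose by 2.53, also relative to the T cell list, where 10 members were lower, and Bhlhe40 (1.93), Prdm1 (1.75) and Batf (1.50) rose over naive cells, while Eomes was at 0.01. The 2 that fell were Nr4a2 (-1.09, adjusted p = 0.136 with its probes averaged) and Zeb2 (-1.66), which has another probe of opposite sign. Of 13 regulatory T cell genes 7 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.98, or -0.66 relative to the T cell list. Ctla4, Il2ra (1.35) and Foxp3, the lineage factor of regulatory T cells (0.98 ± 0.18, adjusted p = 0.0303), rose and Gpr83 (-1.67) fell. None of the 13 was higher and 7 were lower relative to the T cell list, with Foxp3 at -0.66, Il2ra at -0.29 and Ctla4 at 0.21 (adjusted p = 0.516). The Th2 list had 3 of 10 genes higher and 2 lower, the same adjusted over the list alone, with a median of 0.13, or -1.51 relative to the T cell list. Gata3 rose by 1.69 and Il4 fell by 1.64. In the Th17 list 2 of 8 rose and none fell, the same adjusted over the list alone, with a median of 0.71, or -0.93 relative to the T cell list, and Rora (2.50) rose on both scales while 6 members were lower on the second. In the follicular helper list 4 of 10 rose and 3 fell, the same adjusted over the list alone, with a median of 0.45, or -1.19 relative to the T cell list, and the factor gene Bcl6 fell by 1.19. On the scale of the T cell list 1 activation gene was higher and 7 lower, 1 inhibitory receptor gene higher and 9 lower, no Th2 gene higher and 9 lower, and no follicular helper gene higher and 7 lower. Among the genes that rose over naive cells Cd28, Icos, Il2rb, Bhlhe40, Prdm1 and Gata3 did not pass on that scale, and Entpd1 (-0.37) and Batf (-0.14) turned.

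Genes tied to naive or quiescent T cells were mixed. Of 23 genes 6 rose and 4 fell (8 and 5 adjusted over the list alone), with a median of 0.30, or -1.34 relative to the T cell list. Dapl1 (1.98), the egress receptor gene S1pr1 (1.90) and the chromatin organizer gene Satb1 (1.50) rose, and Lrig1 (-2.41) and Igfbp4 (-1.77) fell. No member was higher and 17 were lower relative to the T cell list, where Dapl1 and S1pr1 did not pass and Satb1 was at -0.14. The chemokine receptor gene Ccr7 (0.49) and the factor genes Lef1 (0.19) and Tcf7 (0.10) did not pass. Of 40 cell cycle genes 1, Kif11 (0.83), rose and 4 fell (1 and 2 adjusted over the list alone), with a median of -0.08, which lay above 0 with median centring, or -1.71 relative to the T cell list, where all 40 were lower. The median of all genes on that scale was -1.67. If other cells gave cell cycle transcripts to the naive RNA, these are in the ratios on both scales. The ratios therefore do not show whether the transferred T cells cycled more than naive T cells.

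In spleen alone, 648 genes were at least 2-fold higher and 994 at least 2-fold lower in transferred than naive cells on both arrays. The highest were Klk1b5, a kallikrein gene, at 4.74 ± 0.26 (SD between the 2 arrays), Cxcr6 at 4.06 ± 0.21, S100a4 at 3.96 ± 0.67, Cox6a2, a subunit of cytochrome c oxidase, at 3.43 ± 0.15, and Ifng at 3.42 ± 0.26. The lowest were Mpo at -5.76 ± 0.03, Ctsg (-5.41), Rhd (-5.34), Tal1 (-5.24) and Slc38a5 (-5.17). T cell identity genes had a median of 1.81 in this sample, neutrophil genes -3.55 and Siglech, a marker of plasmacytoid dendritic cells, was at 3.13. No test was possible with 1 sample, and the counts were 425 and 604 with median centring in place of loess, and 11 and 15812 relative to the T cell list.

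In lymph node alone, 560 genes were at least 2-fold higher and 1041 at least 2-fold lower on both arrays. Zmynd15, a zinc finger gene, was highest at 4.60 ± 0.06, followed by Cxcr6 (4.14 ± 0.23), the chemokine gene Ccl8 (3.93 ± 0.07), Il18r1 (4.04 ± 0.26) and Marco, a macrophage scavenger receptor gene (3.34 ± 0.08). The lowest were S100a9 at -7.18 ± 0.76, Chil3 (-6.49), Camp (-6.27), Rhd (-5.77) and Tal1 (-5.76). T cell identity genes had a median of 1.46 here, neutrophil genes -4.61 and erythroid genes -3.01. Counting both organs, 376 genes were at least 2-fold higher on all 4 arrays and 813 lower. Independent lists of these sizes would share 21.0 and 59.9, and simulated unchanged organs measured against the same naive RNA shared 10 and 9. The simulated naive deviation was only as large as that of an organ sample. It held no shift of a whole list like that of the neutrophil genes, at -4.61 here. The simulated counts therefore cannot show how much of the overlap comes from the naive RNA. The naive RNA cannot be split, and part of the overlap may come from it. The lymph node counts were 349 and 650 with median centring and 35 and 14262 relative to the T cell list, and the higher count was 927 with the scanner software's processed signals and 923 with the series table.

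The second comparison sets lymph node against spleen within each dye orientation, so that the naive RNA cancels. In both orientations 69 genes were at least 2-fold higher in lymph node and 220 at least 2-fold lower. Highest in lymph node were Zmynd15 (4.68 ± 0.05, SD between the 2 orientations), Ccl8 (4.02 ± 0.06), Marco (3.24 ± 0.04), the neuropilin gene Nrp2 (3.09 ± 0.13), Anxa3 (2.88), Strip2 (2.66), Lima1 (2.45), Fnbp1l (2.22), the chemokine gene Cxcl9 (2.15) and Apol7c (2.12). Another probe of Nrp2 had the opposite sign over naive cells. Lowest were the immediate early gene Fos (-3.87 ± 0.06), the platelet chemokine genes Pf4 (-3.34 ± 0.44) and Ppbp (-3.09), the chemokine gene Ccl4 (-3.07), the protease gene Ctsl (-3.06), the NF-kB regulator gene Tnfaip3 (-2.93), Klk1b5 (-2.93), S100a9 (-2.91), Amy1 (-2.86) and Upb1 (-2.82). All values are log2 differences of 1 lymph node and 1 spleen sample, with no test of the difference.

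Several lists differed between the organs in value. In the immediate early and heat shock list 14 of 16 genes were lower in lymph node in both orientations and 7 of them at least 2-fold, with a median difference of -0.96. Jun (-2.57), Dusp1 (-2.46), Junb (-1.88) and Egr1 (-1.84) stood beside Fos. Against naive cells that list had 1 gene higher and 3 lower of 16 (0 and 2 adjusted over the list alone), and all 16 were lower relative to the T cell list, with a median of -2.19. All 40 cell cycle genes were higher in lymph node in both orientations, by a median of 0.54, with none at least 2-fold. Melk, a mitotic kinase gene, was 0.99 higher, Ccnb1 0.97 and Mki67, the gene of the proliferation marker Ki-67, 0.70. In the dendritic cell list 8 of 12 genes were lower in lymph node in both orientations, 5 of them at least 2-fold, and 4 were higher, 1 of them at least 2-fold, with a median difference of -0.77. Siglech was at -1.93, the class II genes H2-Ab1 at -1.58 and H2-Aa at -1.21, and the chemokine gene Ccl22, not well above background in spleen, was at least 2.54-fold higher in lymph node. Against naive cells 3 of its 12 genes rose and 1 fell, the same adjusted over the list alone, with a median of 0.42, or -1.22 relative to the T cell list, where none was higher and 10 were lower. The megakaryocyte and platelet list had a median difference of -1.05, with 7 of 8 genes lower and 1 higher in both orientations, and the Th17 list of -0.78, with 7 of 8 lower, including Il22 at -2.02. In the neutrophil list 10 of 12 genes were lower in lymph node and 2 higher in both orientations, 5 of them at least 2-fold lower, with a median difference of -0.85. T cell identity genes had a median difference of -0.33, with 14 of 15 lower and 1 higher. The other medians kept their direction relative to the T cell list. The numbers of genes at least 2-fold apart were 108 higher with no normexp offset, 164 higher and 351 lower with the processed signals, 165 and 352 with the series table, and 258 and 102 relative to the T cell list.

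**Figure D3:**
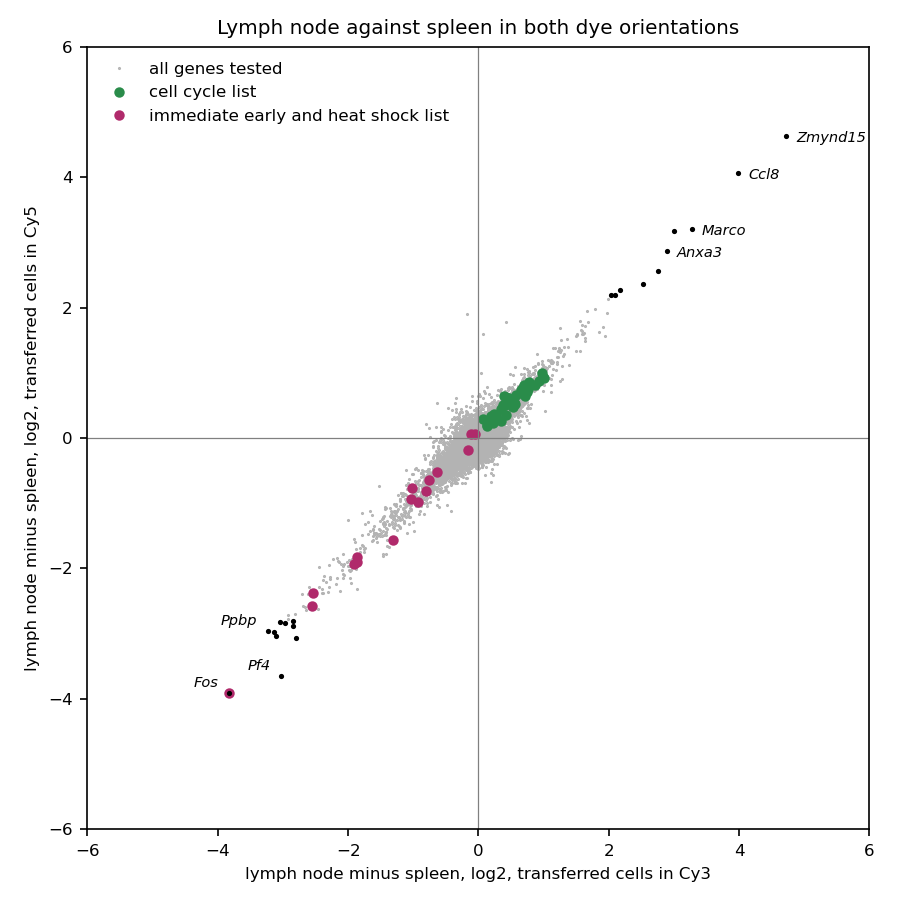
Lymph node minus spleen log2 ratio with the transferred cells in Cy3 (horizontal axis) against the same difference in Cy5 (vertical axis) for all 17267 genes, with the cell cycle and the immediate early and heat shock lists in colour and the 10 highest and 10 lowest genes in black. All 40 cell cycle genes lie above 0 on both axes, and 14 of 16 immediate early and heat shock genes lie below 0 on both.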

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

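Of the tests in this part, those of dye bias, of a handling response, of T cell receptor signalling and of macrophages in the lymph node sort were chosen after their result, or part of it, had been seen, as were all those relative to the T cell identity list. The second marker lists were written down before their values were looked at, with exceptions. Myc in the handling list, Pf4 in the macrophage list and most of the T cell receptor genes had been seen. The intervals given below with the share of a list treat its genes as independent trials. They are too narrow where genes of a list are regulated together. They do not measure the spread between samples or animals.

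Several genes and lists lay on opposite sides of 0 in the 2 organs on all arrays, and these differences were not tested. Higher than naive cells in spleen and lower in lymph node were Amy1 (2.22 against -0.64), Ccl4 (0.84 against -2.24), Ctsl (2.22 against -0.83), Pf4 (0.65 against -2.69), Ppbp (2.64 against -0.45) and Tnfaip3 (1.63 against -1.31). Lower in spleen and higher in lymph node were Ccl8 (-0.0882 against 3.93), Cxcl9 (-0.46 against 1.69), Fnbp1l (-1.0 against 1.22), Lima1 (-0.58 against 1.87), Nrp2 (-1.23 against 1.87) and Zmynd15 (-0.0745 against 4.60). On the scale of the T cell identity list Ccl4 (-1.01 and -3.67), Pf4 (-1.20 and -4.12), Tnfaip3 (-0.22 and -2.74) and Fnbp1l (-2.85 and -0.21) lay below 0 in both spleen and lymph node, and the other genes named stayed on opposite sides. Among all genes, 1157 of 17267 had opposite signs in this way. The list medians did so for cell cycle (-0.38 in spleen, 0.19 in lymph node), immediate early and heat shock (0.10 and -1.13), lymph node and spleen stroma (-0.0372 and 0.0756) and megakaryocyte and platelet genes (0.28 and -0.85), and all of these medians lay below 0 in both organs relative to the T cell identity list.

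Probes that the gene counts left out, because they had no single gene name, also carried signal. Among 5809 such probes that passed the filter, 49 were at least 2-fold higher in transferred cells on all 4 arrays and 227 at least 2-fold lower.

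The first pattern is the low ratio of erythroid and neutrophil genes in both organs. Dye bias is argued against, since a dye effect cancels in the mean of each pair and all 24 genes of the 2 fixed lists fell in those means. The sign turned between orientations in 0.0% of the 24 (exact 95% interval 0.0 to 14.2%), which such low means had nearly fixed in advance. A candidate explanation is erythroid and granulocyte precursor cells in the naive RNA: of 27 measured genes of a second list, none of them in a fixed list, 26 fell (96.3%, interval 81.0 to 99.9%), against 20.5% of all genes, and abundant transcripts such as Lyz2 (-3.88) and Hba-a1 (-3.54) were low too. T cell transcripts may at the same time be diluted in the naive RNA, as 17 of 18 genes of a second T cell list rose (94.4%, interval 72.7 to 99.9%, median 1.27), against 13.1% of all genes. A rise of T cell genes in the transferred cells themselves stays open and untested, and the labels describe a sort for the recovered cells but none for the RNA of the naive cells.

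The second pattern is the low level of immediate early genes in lymph node against spleen. For a general handling response in the spleen cells, 13 of 14 genes of a second list were lower in lymph node in both orientations (92.9%, interval 66.1 to 99.8%, median -0.89), against 38.3% of all genes, but 16 of 18 second-list T cell genes (median -0.24) and 14 of 15 T cell identity genes (median -0.33) were lower too. Relative to the T cell identity list 9 of the 14 were lower (64.3%, interval 35.1 to 87.2%, median -0.484), against 5.02% of all genes. Both intervals lie above the share of all genes, so in these samples this list was lower in lymph node more often than genes at large. That does not tell handling from the organ itself or from other cells in the spleen sort, so the explanation stays open. Stronger T cell receptor signalling in spleen stays open. Of 13 induced genes 7 were lower (53.8%, interval 25.1 to 80.8%), against 38.3% of all genes. Relative to the T cell list 2 of 13 were lower (15.4%, interval 1.92 to 45.4%), against 5.02% of all genes. Each interval holds the share of all genes on its scale, so neither scale decides. The organ itself and other cells in the spleen sort also stay open and were not tested for these genes.

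The third pattern is the difference in myeloid and dendritic cell genes. Plasmacytoid dendritic cells in the spleen sort are a candidate explanation: 10 of 10 genes of a second list were lower in lymph node in both orientations (100%, interval 69.2 to 100%), with a median of -1.68, Tcf4 at -2.24 and Spib at -1.63, and 9 of 10 relative to the T cell list (90.0%, interval 55.5 to 99.7%), while 9 of the 10 were also well above background in naive RNA. A sort on CD4 would remove such cells only as far as they lack CD4, which part of the mouse plasmacytoid dendritic cells carry. For macrophages in the lymph node sort, 5 of 11 genes were higher in lymph node (45.5%, interval 16.7 to 76.6%), or 8 relative to the T cell list (72.7%, against 87.4% of all genes), which leaves that open: C1qc was 0.91 higher and Lyz2 0.34 lower (-0.34). Relative to the T cell list C1qc stayed higher in lymph node (-1.896 in spleen, -0.5748 in lymph node). Lyz2 turned to slightly higher there (-5.555 in spleen, -5.486 in lymph node). Expression of Marco, Ccl8 or Zmynd15 by the T cells of the lymph node stays open as well, untested.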

How the results depend on the processing

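The test that subtracts the median of the T cell identity list from every gene on each array was chosen after seeing the data, and the others were listed before. Under those listed before, 116 of 130 counts stayed within 1.5 times the value given, no list median that lay in the outer tails of its random lists reversed, and neither did any of the 95 genes that passed the test and were run or of the 40 values named by size. Within their spread stayed 687 of 868 list medians and 389 of 520 values named by size, and the others moved further. Medians near 0 changed sign under at least 1 of them for cell cycle, oxidative phosphorylation and stroma over both organs, and for cytotoxic effector, glycolysis, oxidative phosphorylation and trafficking between the organs. Of 1519 values of the 95 genes, 1508 kept their side of the threshold. The other 11 were those of Ifng (adjusted p = 0.0584 without background correction, 0.0503 with no normexp offset, 0.0696 without the trend), Mcm6, Cxcr4 and Lamp1 (0.145, 0.0622 and 0.109 with median centring), Lamp1 and Hmgcs1 (0.0597 and 0.0601 without lymph node array 1), Nr4a2 (0.136 with its probes averaged) and Ldha (0.0704 without spleen array 2, 0.076 without lymph node array 2). Genes named without passing, and organ differences of list members, were not run. Leaving out each array gave 4641 to 6156 changed genes. Aquantile leaves within-array ratios as they are and gave 5801, and leaving out saturated probes gave the same 5802 genes, so neither tests much. A slide or scan block was not run because all arrays share 1 slide and 1 scan. No paired analysis was possible because each organ is 1 sample once its dye exchange is averaged, and the array numbers mark the dye orientation. Signal over background limits dim genes: the offset of 50 pulls their ratios towards 0.

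With the 4 arrays as separate samples, 12954 genes changed, 5741 higher and 7213 lower, because that fit measures only the spread between arrays, and they held all 5802 genes of the test on 2 organs. Median centring gave 425 higher and 604 lower in spleen and 349 and 650 in lymph node. The processed signals gave 927 higher in lymph node, and 164 higher and 351 lower in lymph node than spleen, and the deposited log10 ratios gave 923, 165 and 352. With no offset 108 genes were higher in lymph node than spleen. For these the cause was not tested.

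Relative to the T cell identity list, by construction nearly every gene moved down: 16646 genes changed (48 higher, 16598 lower), 11 were at least 2-fold higher and 15812 lower in spleen, 35 and 14262 in lymph node, and 258 higher and 102 lower in lymph node than spleen. Medians over both organs turned to -0.557 for activation and costimulation, -0.525 CD8, -1.15 cholesterol synthesis, -0.21 cytotoxic effector, -1.22 dendritic cell, -1.02 effector and exhaustion factors, -1.19 follicular helper, -0.882 inhibitory receptors, -1.23 interferon gamma, -1.34 naive and quiescence, -0.655 regulatory T cell, -0.531 Th1, -0.93 Th17, -0.566 trafficking, -1.33 type I interferon and -1.25 unfolded protein response, and, for lists outside the outer tails, to -1.51 Th2, -1.44 glycolysis, -1.39 apoptosis regulators and -1.63 stroma. Lymph node minus spleen turned to 0.22 for activation and costimulation, 0.26 B cell, 0.25 cholesterol synthesis, 0.0828 effector and exhaustion factors, 0.25 macrophage and monocyte, 0.24 Th2 and 0.118 type I interferon, and, outside the outer tails, to 0.402 cytotoxic effector, 0.294 Th1, 0.281 follicular helper, 0.296 naive and quiescence, 0.333 inhibitory receptors, 0.336 trafficking, 0.371 glycolysis, 0.353 apoptosis regulators, 0.33 erythroid and 0.282 melanocyte and melanoma. Of the 95 genes, 22 turned: Cd4 (-0.0544), Gzmk (-0.103), Fasl (-0.21), Nkg7 (-0.0262), Il12rb2 (-0.439), Foxp3 (-0.655), Il2ra (-0.288), Satb1 (-0.141), Batf (-0.14), Cd8b1 (-0.0242), Kif11 (-0.808), Pfkp (-0.278), Ldha (-1.07), Sc5d (-0.533), Bcl2l1 (-0.422), Eno1 (-0.619), Entpd1 (-0.374), Gbp4 (-0.358), Hmgcs1 (-1.11), Ifit3 (-0.828), Klrd1 (-0.49) and Pmaip1 (-0.257). Another 16 kept their sign but lost their call, with adjusted p from 0.0608 to 0.863: Thy1, Lck, Cd3d, Gzmc, Stat4, Gata3, S1pr1, Dapl1, Cd28, Icos, Il2rb, Ctla4, Bhlhe40, Prdm1, Klrc1 and Serpinb9. Cd4, Thy1, Lck and Cd3d belong to the list that sets this scale, so their loss of sign or call is largely fixed by construction. The other 57 kept sign and call.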

Other observations

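Of 18 cholesterol synthesis genes 10 rose and none fell (10 and 1 adjusted over the list alone), with a median of 0.49, or -1.15 relative to the T cell list. Sc5d rose by 1.11 and Hmgcs1, early in the pathway, by 0.53 (adjusted p = 0.0601 without lymph node array 1). In the glycolysis list 6 of 18 rose and 1 fell (8 and 2 adjusted over the list alone), with a median of 0.20, or -1.44 relative to the T cell list, led by Pfkp (1.36) and Eno1 (1.02), with Hk1 at -0.84. No gene of 25 in oxidative phosphorylation rose and 4 fell (0 and 0 adjusted over the list alone), with a median of -0.11, which lay above 0 with median centring or with probes averaged, or -1.75 relative to the T cell list. The type I interferon list had 8 of 24 genes higher and 3 lower (8 and 4 adjusted over the list alone), with a median of 0.31, or -1.33 relative to the T cell list. Ifit3 rose by 0.81 while Oasl1 fell by 1.14. In the interferon gamma list 6 of 18 rose and 2 fell, the same adjusted over the list alone, with a median of 0.41, or -1.23 relative to the T cell list, and Gbp4 rose by 1.28 while Iigp1 fell by 1.95. The unfolded protein response list had 4 of 14 higher and none lower, the same adjusted over the list alone, with a median of 0.39, or -1.25 relative to the T cell list. Its median difference between lymph node and spleen was -0.42, or -0.0114 relative to the T cell list. Of 17 apoptosis regulators 4 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.25, or -1.39 relative to the T cell list, and the rises included Pmaip1 (1.38) and the survival gene Bcl2l1 (1.22). None of the genes named here as rising stayed above 0 relative to the T cell list, and no member of these lists was higher on that scale, while 17 cholesterol synthesis, 15 glycolysis, 25 oxidative phosphorylation, 24 type I interferon, 17 interferon gamma, 13 unfolded protein response and 14 apoptosis genes were lower. As 16598 of 17267 genes were lower there, with a median of -1.67 over all genes, these counts say little about the lists.

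The natural killer receptor list was mixed. Of 14 genes 4 rose and 5 fell (5 and 6 adjusted over the list alone), with a median of -0.36. The receptor genes Klrc1 (1.91) and Klrd1 (1.15) rose, and Klra7 (-2.17), Klrb1c (-1.67) and Ncr1 (-1.04) fell. Relative to the T cell list none of the 14 was higher and 12 were lower. Klrc1 did not pass there (0.27, adjusted p = 0.39) and Klrd1 was at -0.49. In the CD8 list Cd8b1 rose by 1.61 (2.14 in spleen, 1.09 in lymph node) and Cd8a, at 0.61, did not pass, and adjusted over the list alone 1 rose too. Relative to the T cell list Cd8b1 was at -0.02 (limma adjusted p = 0.94) and Cd8a at -1.03 (limma adjusted p = 0.00426), with a list median of -0.53. Cd8a lay above the median of all genes there (-1.67), so its lower call says little. None of 6 measured melanocyte and melanoma genes passed, also adjusted over the list alone, with a median of -0.09, or -1.73 relative to the T cell list, where all 6 were lower. The median of all genes on that scale was -1.67. In the stroma list 1 of 10 rose and 2 fell (0 and 2 adjusted over the list alone), with a median of 0.01, or -1.63 relative to the T cell list, where 9 were lower. In the megakaryocyte and platelet list 1 of 8 rose and 1 fell (1 and 2 adjusted over the list alone), with a median of -0.43, and none was higher and 6 were lower relative to the T cell list, with a median of -2.07.

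Some members of the fixed lists, picked here after their values were seen, lay apart between the organs. Ifng was -2.09 lower in lymph node than spleen, Il22 -2.02, Il10 -1.44 and Tnf -1.04, while Gzmc was 1.44 higher, Ccr7 1.36 higher and Itgae, the integrin chain that binds E-cadherin, 1.22 higher in lymph node. In spleen alone Il22 was at 1.96, Ccr6 at 1.24 and Il1r1 at 1.20 over naive cells, and in lymph node at -0.06, 0.12 and 0.21. Relative to the T cell list the spleen values were 0.12 for Il22, -0.60 for Ccr6 and -0.65 for Il1r1. These differences were not tested, and each rests on 1 sample per organ.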
